A study of Escherichia coli with 3 samples.

How the data were processed

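The data were log2 ratios from 3 two-colour arrays of spotted oligonucleotides, each hybridised with cDNA from triclosan-exposed and from untreated E. coli K-12 MG1655. The dyes were taken from the labels, with the triclosan RNA in Cy3 on arrays 1 and 2 and in Cy5 on array 3. Per the submitters' processing notes limma was used, with no version or role given. The scanner, background correction and normalization are not given in the sources used here. The values as deposited by the authors are on a log2 scale, as seen from spots at the log2 of ratios of small whole numbers. The columns were neither centred nor brought to one scale, with medians of -0.103, -0.258 and -0.56 on arrays 1 to 3. Which channel stands over which stays unknown. Such an offset moves every gene of an array and so moves counts of calls per side. Its cause was not tested.

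Each array has 14400 spots, of which 636, 1542 and 824 on arrays 1 to 3 had no value (4.42%, 10.71% and 5.72%). A further 166, 366 and 153 spots held a value of 16.61 in size, the log2 of 100000. These were read as marks for a spot with no signal in 1 channel and treated as not measured, a choice made after the data were seen, and keeping them as ratios was added as an alternative. Spots were named through the platform annotation, which can be old. A single gene symbol was given for 6412 spots, several for 48 and none for 7940, and spots with several or none were left out of the gene tests. Symbols were updated through the gene ID with a K-12 gene table of assembly ASM584v2, which matched 3197 of 3206 genes, while 9 kept the annotation's name. That table served for names and for which genes are neighbours, and coordinates are not given because the array names no genome build. Each gene had 2 spots, averaged per array. The r between the 2 spots of a gene across genes was 0.965, 0.828 and 0.943 on arrays 1 to 3, with an SD between them of 0.23, 0.51 and 0.27 on the log2 scale.

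By a rule set before the data were examined, a negative correlation of array 3 with both others meant that the columns were read as dye ratios, so arrays 1 and 2 were multiplied by -1. Each array was counted as 1 replicate. A gene was tested if measured on all 3 arrays, which left out 32 genes. The test was two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the ratios as deposited, an intercept as the only term and Benjamini-Hochberg adjustment over 3174 genes at a threshold of 0.05. In this fit eBayes shrank every gene to one SD of 0.62, since the arrays' offsets enter the spread of every gene, so a gene with a large spread of its own can still pass. The planned fit on arrays centred on their medians has a variance for each gene (prior SD 0.28 with 3.15 degrees of freedom). Values in the text are centred means ± SD, whereas calls and adjusted p are from the deposited scale unless centring is named.

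Gene lists were 35 sets of textbook genes and regulons, tested where at least 5 members were measured. The test was limma's camera with a preset correlation of 0.01, which compares a list with the other genes, and camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also takes its degrees of freedom from the 3 arrays and not from the number of genes. fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Genes named are the 10 furthest out on the deposited scale on each side among those past the threshold with the same sign on 3 arrays, the 3 members of largest size on the deposited scale in each list, and fabI, fabA, fabB, fabR, fadR, marA, soxS, acrA, acrB, tolC, ompF and rpoS whatever their values. In 14 lists the 3 members of largest centred size are not the same 3. Any other gene named was chosen after its values were seen.

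The scripts were tested on simulated data of 3174 genes, 200 of them changed, with the spread of these arrays and each gene drawn independently. On the deposited scale 47% of genes changed 2-fold and 97% of those changed 4-fold were recovered, and 0.98% of unchanged genes were called. After centring these shares were 57%, 92% and 0.17%. In the data themselves 38.5% of genes were called, far more than were changed in the simulation, so these shares may not carry over. Alternatives were another orientation of array 3, a dye term, each array left out, centring, scaling, single spots, genes on 2 arrays, robust eBayes, array weights, an ordinary statistic, an adjusted p of 0.1, treat with a 1.2-fold change, a 1.5-fold rule, no rule on signs, adjustment over the lists' genes, rank correlation, and camera on ranks. A planned comparison with probes for genes of other strains was not run, since the annotation used here does not mark such probes. Figures and counts of spots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.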

Results

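Gene expression was compared between Escherichia coli K-12 MG1655 exposed for 30 min to 0.12 mg/L triclosan and untreated cells, both in MOPS minimal medium at 37 C. Triclosan is a biocide whose known target is FabI, the enoyl-ACP reductase of fatty acid synthesis, and the dose is named in the labels as its minimum inhibitory concentration. The drug was added at an OD600 of 0.7. Each of 3 two-colour spotted oligonucleotide arrays held RNA of treated and of untreated cells. The triclosan RNA was labelled with Cy3 on arrays 1 and 2 and with Cy5 on array 3. The design text names 3 independent RNA extractions and also a dye swap, and does not say whether array 3 came from an extraction of its own. The limma p-values of genes rest on the spread between these 3 arrays, part of which may be technical. On the deposited scale that spread is a single SD shared by all genes. The SD printed for a gene therefore does not enter its p there. The number of arrays limits the precision. The p-values of camera with its preset correlation of 0.01 rest on the spread between genes, taken as nearly independent. A small camera p is therefore no measure of agreement between arrays. Estimated correlations within lists ran from 0.24 to 0.86 on the deposited scale and from -0.09 to 0.4 after centring. Of 3206 genes named on the arrays, 3174 had a value on all 3.

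The direction of the ratios is not settled, so the values below carry no statement that a gene was higher or lower with triclosan. As deposited, array 3 mirrored arrays 1 and 2 over all spots (Pearson's r across spots of -0.866 and -0.739), whereas arrays 1 and 2 ran together (r of 0.744). Arrays 1 and 2 were therefore turned to the orientation of array 3. Genes are placed on the "flagellar side" (positive values, the sign of fliC) or on the "iron uptake side" (negative values), names chosen after the data had been seen. If the columns hold Cy5 over Cy3, the flagellar side was higher with triclosan, and if they hold Cy3 over Cy5, it was lower. The marks for no signal argue against both if only an empty upper channel is marked. They do not decide if either channel can be marked, as set out in the closing part, and the direction stays open there too. The sizes, the counts and which genes lie on opposite sides do not depend on which RNA was on top.

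Flagellar and nitrate respiration genes lay furthest out on one side, and ribonucleotide reductase and iron uptake genes on the other. Of the 3174 genes tested with limma, 1222 (38.5%) passed an adjusted p of 0.05, with 834 on the flagellar side and 388 on the iron uptake side. The median gene was itself shifted to 0.24, with array medians of 0.51, 0.48 and -0.25, so gene and list values below are centred log2 ratios, relative to the median gene of each array. On the deposited scale 68.2% of the calls lay on the flagellar side, and after centring 50.9% did, with 906 genes on the flagellar side and 875 on the iron uptake side. At least a 2-fold size with the same sign on 3 arrays was seen for 967 genes (664 on the flagellar side and 303 on the iron uptake side), and after centring for 905 (478 and 427). The same sign on 3 arrays was seen for 58.3% of genes, and for 76.1% after centring, on arrays turned by their correlations. Across genes, which are not independent replicates, r was 0.821 between arrays 1 and 2, 0.937 between arrays 1 and 3 and 0.838 between arrays 2 and 3. Without array 1 the count of genes past the threshold was 637, of which 376 lay on the flagellar side. Without array 2 the flagellar side held 515 genes, and without array 3 the iron uptake side held 251. Calls with 1 array left out, here and below, are on the deposited scale unless centring is named. There the opposed offsets of the arrays also enter the spread.

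**Figure D1:**
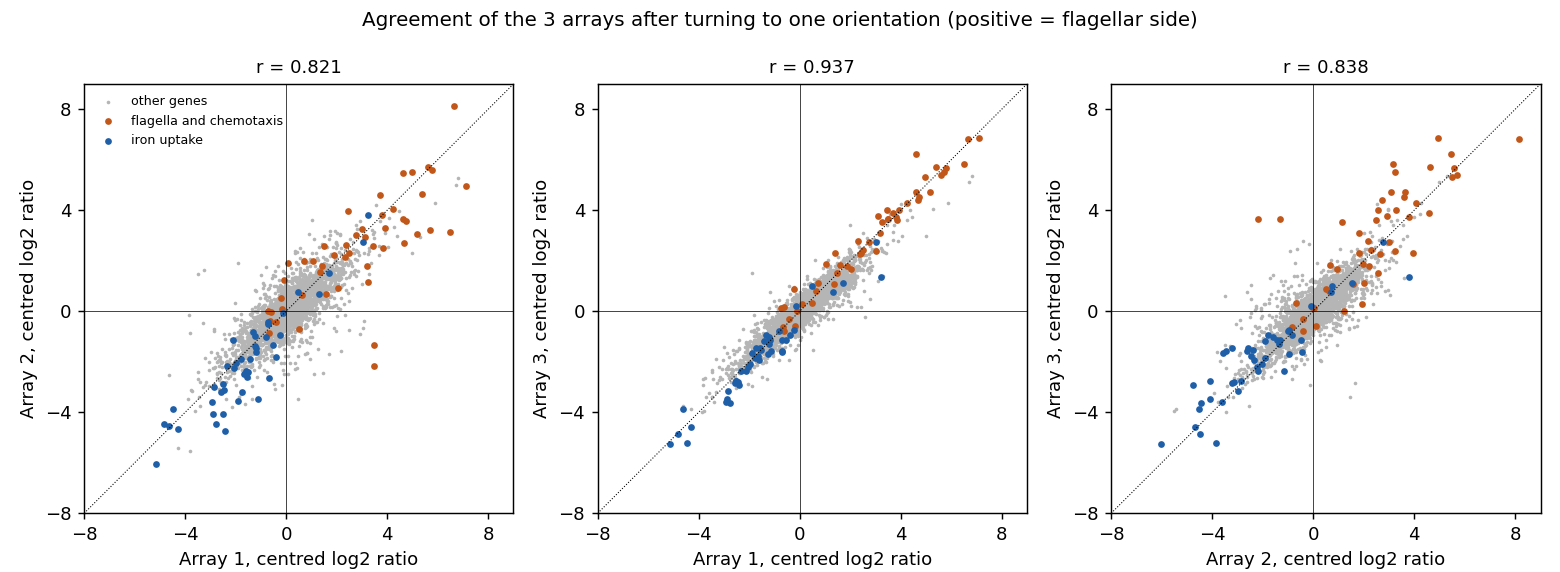
Each panel sets the centred log2 ratios of 2 arrays against each other for 3174 genes after turning to one orientation, with the flagella and chemotaxis list in orange, the iron uptake list in blue and the dotted line marking equal values. The points follow the line with r of 0.821, 0.937 and 0.838, and scatter most on array 2.

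Motility genes held the furthest values on the flagellar side. fliC, the flagellin gene, lay at 7.20 ± 0.82 (SD, n = 3), a 147-fold size, and flgB, a basal body rod gene, at 6.32 ± 1.18. fliA, the sigma factor of the late flagellar genes, lay at 5.68 ± 0.10, motB of the stator at 5.57 ± 0.16 and cheA, the chemotaxis kinase, at 5.26 ± 0.28. The basal body and hook genes flgC (5.43 ± 0.80), flgF (5.25 ± 0.56) and flgE (5.16 ± 1.77) completed the motility members of the 10 genes furthest out. Of 49 flagella and chemotaxis genes measured, 40 passed on the flagellar side and 9 did not pass, and the counts were 40 and 9 adjusted over the list alone. The list's median was 2.64 (camera adjusted p = 4.15e-44; adjusted p = 0.93 with an estimated correlation). After centring, 37 members passed on the flagellar side and 2 on the iron uptake side, namely fliE and aer, which were picked out after their values were seen.

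Respiratory genes lay on the flagellar side both for anaerobic and for aerobic chains. The nitrate transporter gene narK (5.82 ± 0.86), the nitrate reductase gene narG (5.60 ± 0.97) and the nitrite reductase gene nirB (4.81 ± 0.93) led the anaerobic list, in which 35 of 58 genes passed on the flagellar side, 6 on the iron uptake side and 17 did not pass. Adjusted over the list alone these counts were 36, 6 and 16, and the median was 0.83 (camera adjusted p = 8.89e-08; adjusted p = 0.93 with an estimated correlation). The members on the iron uptake side included hycA and hycB of the formate hydrogenlyase operon. Of 27 genes for aerobic respiration and ATP synthase, 26 passed on the flagellar side and 1, ndh, on the iron uptake side, with the same counts adjusted over the list alone. The largest sizes there were those of the ATP synthase genes atpB (2.36 ± 0.34) and atpA (1.96 ± 0.24) and of the cytochrome bo oxidase gene cyoB (1.95 ± 0.65). The list's median was 1.46 (camera adjusted p = 2.15e-07; adjusted p = 0.93 with an estimated correlation). ndh, the other NADH dehydrogenase of this organism, lay at -1.58 ± 0.17.

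**Figure D2:**
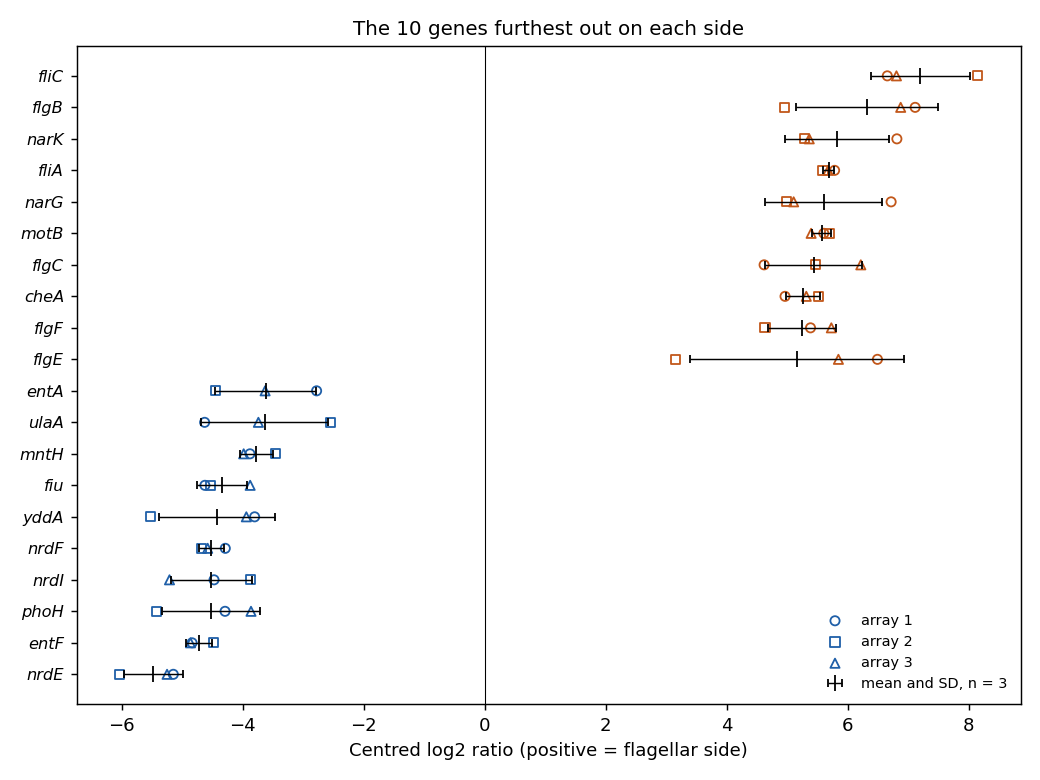
Centred log2 ratios of the 10 genes furthest out on each side, with an open symbol for each array and a bar for the mean ± SD (n = 3). fliC lies at 7.20 ± 0.82 and nrdE at -5.48 ± 0.49 (genes with 1 sign on the 3 arrays were chosen).

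Genes of protein and nucleotide synthesis lay together on the flagellar side. Of 54 ribosomal protein genes, 49 passed there and 5 did not pass (52 and 2 adjusted over the list alone), with a median of 1.37 (camera adjusted p = 4.1e-12; adjusted p = 0.93 with an estimated correlation). rplW (2.08 ± 0.31), rplY (2.06 ± 0.13) and rplC (2.03 ± 0.70) had the largest sizes. Of 27 purine and pyrimidine genes, 25 passed on the flagellar side and 2 did not pass (26 and 1 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 2.15e-12; adjusted p = 0.93 with an estimated correlation). pyrB, the catalytic subunit of aspartate carbamoyltransferase, lay at 3.35 ± 0.17, purM at 3.02 ± 0.73 and purH at 2.55 ± 0.27. Of 14 genes for branched chain amino acids and threonine, 11 passed on the flagellar side and 3 did not pass, also when adjusted over the list alone. ilvC (3.36 ± 0.26), thrA (1.83 ± 0.58) and thrC (1.67 ± 0.34) led that list, whose median was 1.28 (camera adjusted p = 0.00118; adjusted p = 0.93 with an estimated correlation).

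The cold shock list was led by cspG (3.88 ± 0.33), cspB (2.76 ± 0.12) and cspI (2.54 ± 0.55), which code for small RNA-binding proteins. Of its 16 genes, 12 passed on the flagellar side, 1 (hns, the nucleoid protein H-NS) on the iron uptake side and 3 did not pass, and the counts were 13, 2 and 1 adjusted over the list alone. Its median was 1.202 (camera adjusted p = 0.000334; adjusted p = 0.93 with an estimated correlation). Among 68 genes of carbohydrate uptake and use, 27 passed on the flagellar side, 3 on the iron uptake side and 38 did not pass (28, 3 and 37 adjusted over the list alone). The galactitol transporter gene gatC (4.06 ± 0.36), malE for the maltose binding protein (3.73 ± 0.48) and gatZ (3.58 ± 0.55) led it. After centring 27 of these genes passed on the flagellar side and 18 on the iron uptake side. The list's median of 0.16, relative to the median of all genes, was far below its mean of 0.64, relative to their mean. Its camera adjusted p of 0.000781 became 0.123 after centring, 0.119 with a dye term and 0.0524 with camera on ranks (adjusted p = 0.93 with an estimated correlation).

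Fatty acid synthesis genes lay on the flagellar side, whereas the gene of the known target of triclosan did not pass. fabI lay at 0.31 ± 0.53 (SD, n = 3; limma adjusted p = 0.215), with a deposited log2 ratio of 1.04, 1.18 and -0.54 on the 3 turned arrays. Without array 3 it passed (limma adjusted p = 0.0262) at 1.11 on the deposited scale. On that scale the median gene of arrays 1 and 2 itself lay at 0.51 and 0.48. Both these arrays carry the triclosan RNA in Cy3, so the dyes are then not balanced. fabB, which codes for a condensing enzyme needed for unsaturated fatty acids, lay at 2.44 ± 0.11 (adjusted p = 1.72e-12), fabH at 1.11 ± 0.27, accC of acetyl-CoA carboxylase at 1.05 ± 0.22 and fabA at 1.02 ± 0.12. Of 14 genes measured, 9 passed on the flagellar side and 5 did not pass (10 and 4 adjusted over the list alone), with a median of 0.78 (camera adjusted p = 0.0272; adjusted p = 0.93 with an estimated correlation). With no-signal marks kept as ratios the list's adjusted p was 0.0544. The calls of fabH (adjusted p = 0.0946), accC (0.0784) and fabA (0.0673) were lost without array 1, and that of fabA also without array 2 (0.06). fadR, a regulator of fatty acid synthesis and breakdown, lay at 1.19 ± 0.08. The fixed genes fabR, marA and tolC had 0 spots with a single gene symbol in the annotation used here and were not analysed.

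The iron uptake list lay on the side named for it, with 3 of its genes for a ribonucleotide reductase among the furthest out. nrdE, nrdI and nrdF, members of this Fur-controlled list that code for a manganese-dependent ribonucleotide reductase and its partner and not for uptake, lay at -5.48 ± 0.49 (a 44.5-fold size), -4.52 ± 0.67 and -4.51 ± 0.20. Among the uptake genes, entF of enterobactin synthesis lay at -4.73 ± 0.21, the outer membrane receptor gene fiu at -4.34 ± 0.41 and entA at -3.62 ± 0.83. Of 45 genes measured, 32 passed on the iron uptake side, 5 on the flagellar side and 8 did not pass (35, 5 and 5 adjusted over the list alone, and 39, 5 and 1 after centring), with a median of -1.87 (camera adjusted p = 3.09e-20; adjusted p = 0.93 with an estimated correlation). The 5 on the flagellar side were the ferrous iron uptake genes feoA (2.84 ± 0.16), feoB and feoC and the iron storage genes ftnA (2.80 ± 1.27) and bfr, named here after their values were seen. Outside the list, the manganese importer gene mntH lay at -3.77 ± 0.28, phoH at -4.52 ± 0.81, yddA at -4.42 ± 0.96 and ulaA, whose gene ID is not among those of the K-12 gene table, at -3.64 ± 1.05. For comparison, 101 spots were taken to have almost no signal, as they lay at ratios of whole numbers up to 5 on all 3 arrays. Their brightness was not read. They had a median of -0.44 and a 5th percentile of -1.30. Choosing them by such ratios bounds their values, so they set no floor for genes further out.

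The OxyR list also passed on the iron uptake side. As written it shares fhuF and fur with the iron uptake list and dps and katE with the general stress (sigma S) list. These lists are therefore not independent of each other. Of 18 genes, 9 passed there (6 of them fhuF and suf genes), 2 on the flagellar side and 7 did not pass, with the same counts adjusted over the list alone and 9, 3 and 6 after centring. The list's median was -0.68 (camera adjusted p = 0.00118; adjusted p = 0.93 with an estimated correlation). fhuF (-3.49 ± 0.60), a ferric siderophore reductase gene, and sufA (-3.16 ± 0.16), of the Suf pathway for iron-sulfur cluster assembly, were on the iron uptake side. sodB, for iron superoxide dismutase, lay at 3.60 ± 0.94 on the flagellar side. katG, the catalase-peroxidase gene, lay at 0.29 ± 1.36 and did not pass (limma adjusted p = 0.239), and ahpC at 0.50 ± 0.16 did not pass either (0.0868).

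General stress and acid resistance genes lay on the iron uptake side. Of 39 sigma S genes, 27 passed there and 12 did not pass, also when adjusted over the list alone, and 33 passed there after centring, with a median of -1.52 (camera adjusted p = 2.15e-12; adjusted p = 0.93 with an estimated correlation). yeaH (-2.94 ± 0.24), osmY (-2.90 ± 0.19) and the protein kinase gene yeaG (-2.87 ± 0.28) had the largest sizes, and rpoS, which codes for sigma S, lay at -1.51 ± 0.34 (limma adjusted p = 0.00168). Of 18 acid resistance genes, 8 passed on the iron uptake side and 10 did not pass, also when adjusted over the list alone, and 14 passed there after centring. The lysine decarboxylase gene cadA lay at -2.17 ± 0.20, adiY at -1.99 ± 0.20 and gadA, which has a near-identical copy in gadB, at -1.63 ± 0.39. That list's median was -0.94 (camera adjusted p = 0.000788; adjusted p = 0.93 with an estimated correlation). The median of -0.44 of spots taken to have almost no signal lay on this side too.

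**Figure D3:**
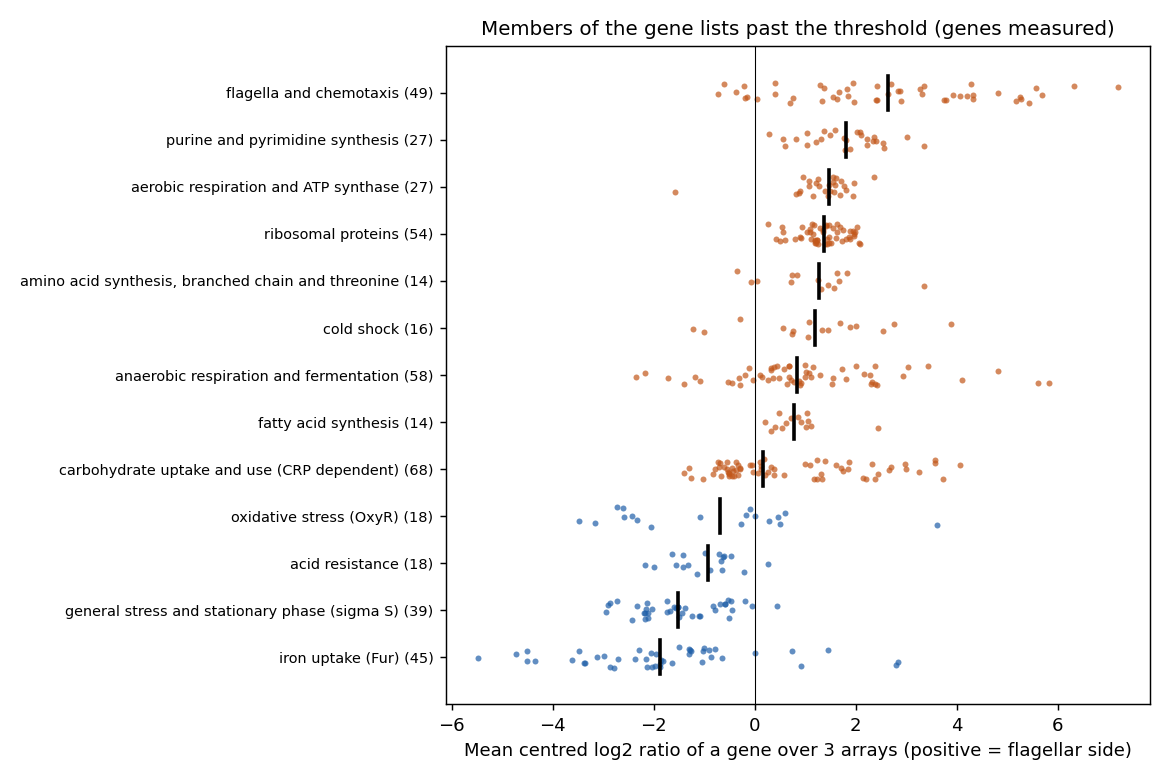
Mean centred log2 ratio over 3 arrays of each gene (points) in the 13 gene lists past the threshold, with a black bar at each list's median and the number of genes measured in brackets. The medians run from 2.64 for flagella and chemotaxis to -1.87 for iron uptake.

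The 35 lists fixed before the data were examined thus split into 13 past the threshold of camera with its preset correlation, 9 on the flagellar side and 4 on the iron uptake side, and 22 that did not pass. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), and fry called 0 (9 at an unadjusted p under 0.05). That form of camera rests on the few degrees of freedom of 3 arrays, so its p-values do not single out correlation within lists. After centring, the flagella list had an estimated correlation of 0.01, the same as the preset. Its camera adjusted p was 1.78e-10 with the preset and 0.44 with the estimate. After centring, camera called 20 lists, 12 of them among the 13, fry called 28, and the lowest adjusted p of camera with an estimated correlation was 0.44. In the paragraphs below "passed" refers to the deposited scale unless centring is named. Without array 3 camera called 20 lists as well.

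Lists of porins, efflux and drug resistance regulators passed in camera neither on the deposited scale nor after centring, although single members had large sizes. fry after centring called porins and lipoproteins (adjusted p = 0.0205) and multidrug efflux (0.0238). In the list of porins and lipoproteins (adjusted p = 0.079, median 0.54), 9 of 20 genes passed on the flagellar side and 1 on the iron uptake side (10 and 1 adjusted over the list alone). The porin gene ompF lay at 3.78 ± 0.73 (a 13.7-fold size), ompW at 2.68 ± 0.72 and tsx at 2.67 ± 0.49. In the multidrug efflux list (adjusted p = 0.387, median -0.10), 4 of 36 genes passed on each side, also adjusted over the list alone. The list also counts murJ (1.02), which entered it through a synonym and is a member of the peptidoglycan list. There mdtN lay at -2.54 ± 0.44, envR at -1.64 ± 0.50 and mprA at 1.07 ± 0.25, and without array 2 mprA did not pass (adjusted p = 0.0557). The main pump genes acrA (0.17 ± 0.07, limma adjusted p = 0.379) and acrB (0.24 ± 0.19, 0.296) did not pass. After centring, 11 porin and lipoprotein genes passed on the flagellar side and 6 on the iron uptake side, and 5 and 11 efflux genes did. Of 27 genes of the MarA, SoxS and Rob regulon (adjusted p = 0.387, median -0.03), 3 passed on the flagellar side and 4 on the iron uptake side, also adjusted over the list alone, and 3 and 7 after centring. soxS lay at -1.70 ± 0.51 and ygiC at 1.25 ± 0.16, while sodA, for manganese superoxide dismutase, lay at -2.29 ± 1.93, and its deposited ratio had the opposite sign on array 2. Without array 3 neither sodA (adjusted p = 0.288) nor soxS (0.0617) passed.

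Of 4 further envelope lists, none passed in camera on the deposited scale and 3 did after centring, with adjusted p of 0.0055 for Rcs and colanic acid, 0.01 for peptidoglycan and division and 0.0301 for lipopolysaccharide. With an estimated correlation these were 0.44, 0.44 and 0.52. Envelope stress was called after centring by fry (adjusted p = 0.0252) and not by camera (0.39). Of 26 Rcs and colanic acid genes (adjusted p = 0.0522, median -0.42), 4 passed, on the iron uptake side, also adjusted over the list alone, and 22 did not. osmB lay at -1.74 ± 0.04, while wzxC (-1.49 ± 0.97) and wcaI (-1.35 ± 1.33) each had 1 array of opposite sign on the deposited scale. After centring, 10 genes of that list passed on the iron uptake side and 1 on the flagellar side. The call of wzxC was lost without array 1 (adjusted p = 0.0879) or array 3 (0.294), and that of wcaI without array 2 (0.511) or array 3 (0.222). Of 28 envelope stress genes (adjusted p = 0.617, median 0.20), 7 passed on the flagellar side and 1 on the iron uptake side, and 5 passed adjusted over the list alone, all 5 on the flagellar side. After centring 8 passed on the flagellar side and 6 on the iron uptake side. Among them ppiA lay at 1.68 ± 0.18, ppiD at 1.18 ± 0.16 and bamD at 1.08 ± 0.22, and without array 1 ppiD did not pass (adjusted p = 0.0584). Of 38 genes for peptidoglycan and division (adjusted p = 0.104, median 0.30), 11 passed on the flagellar side and 1 on the iron uptake side (10 on the flagellar side adjusted over the list alone, and 14 and 1 after centring), with dacA at 1.76 ± 0.10, mreC at 1.58 ± 0.62 and murA at 1.53 ± 0.26. Of 38 lipopolysaccharide genes (adjusted p = 0.387, median 0.24), 6 passed on the flagellar side, and 2 adjusted over the list alone. After centring 11 passed on the flagellar side and 1 on the iron uptake side. lpxH lay at 1.19 ± 0.17, msbA at 0.84 ± 0.30 and lptE at 0.77 ± 0.18. Without array 1 the calls of msbA (adjusted p = 0.268) and lptE (0.277) were lost, as they were without array 2 (0.0555 and 0.115).

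Of 25 genes for fimbriae, curli and biofilm (adjusted p = 0.0805, median -0.60), 5 passed on the flagellar side and 8 on the iron uptake side (6 and 8 adjusted over the list alone). bhsA lay at -1.97 ± 0.02, the curli regulator gene csgD at -1.55 ± 0.42 and fimC at 1.27 ± 0.75, which did not pass without array 2 (adjusted p = 0.0801). After centring the list passed (camera adjusted p = 0.0397, and 0.44 with an estimated correlation), with 5 genes on the flagellar side and 14 on the iron uptake side. Of 12 phospholipid genes (adjusted p = 0.774, median 0.47), 5 passed on the flagellar side and 2 on the iron uptake side (5 and 3 adjusted over the list alone, and 6 and 3 after centring). cfa, for cyclopropane fatty acid synthase, lay at -1.54 ± 0.16, clsB at -1.42 ± 0.40 and gpsA at 0.89 ± 0.34. clsB did not pass without array 1 (adjusted p = 0.0919) or array 3 (0.0691), nor gpsA without array 1 (0.254) or array 2 (0.0626). Of 11 genes of fatty acid breakdown and the glyoxylate shunt (adjusted p = 0.659, median 0.21), 4 passed, on the flagellar side, and 3 adjusted over the list alone, while after centring 4 passed there and 3 on the iron uptake side. After fadR the largest sizes there were those of fadH (1.10 ± 0.79) and aceK (0.76 ± 0.51), and aceK did not pass without array 1 (adjusted p = 0.104) or array 2 (0.363).

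Among stress lists, 1 of 17 heat shock genes passed (adjusted p = 0.266, median -0.42), namely ibpA at -1.36 ± 0.18, also adjusted over the list alone. After centring 8 passed on the iron uptake side and 2 on the flagellar side, and the list did not pass (camera adjusted p = 0.0939). The chaperone genes dnaK (-1.06 ± 0.01) and groL (0.56 ± 0.05) passed in limma after centring (adjusted p = 0.00221 and 0.0162) and not on the deposited scale (0.0566 and 0.0588), where groL passed without array 3 (0.0275). Of 19 SOS genes (adjusted p = 0.118, median -0.69), uvrD (0.77 ± 0.11) passed over all genes and not adjusted over the list alone, nor without array 1 (adjusted p = 0.245) or array 2 (0.132). After centring the SOS list passed on the iron uptake side (camera adjusted p = 0.0301, and 0.44 with an estimated correlation), with 10 genes there and 1 on the flagellar side. The polymerase genes dinB (-1.07 ± 0.23) and umuC (-1.01 ± 0.28) passed in limma after centring (adjusted p = 0.00357 and 0.00528) and not on the deposited scale (0.0528 and 0.0754). Of 31 genes for detoxification and glutathione (adjusted p = 0.329, median -0.22), 5 passed on each side (5 on the flagellar and 4 on the iron uptake side adjusted over the list alone, and 7 and 11 after centring), with yqjG at -1.92 ± 0.13, nfsB at 1.02 ± 0.11 and grxD at 0.95 ± 0.22. Without array 1 grxD (adjusted p = 0.108) and nfsB (0.0622) did not pass, nor did nfsB without array 2 (0.0521). Of 23 genes for RNA processing and toxin-antitoxin pairs (adjusted p = 0.617), 3 passed on the flagellar side and 2 on the iron uptake side, also adjusted over the list alone, and 6 and 5 after centring. Its median was -0.35. The ribonuclease gene rnb lay at 1.88 ± 0.04, mqsR at -1.32 ± 0.33 and rnc at 0.78 ± 0.21. Without array 1 mqsR (adjusted p = 0.116) and rnc (0.259) did not pass, nor did rnc without array 2 (0.151).

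Lists of growth and central metabolism had medians above 0 and did not pass on the deposited scale. After centring, translation factors and RNA polymerase (camera adjusted p = 0.00318) and DNA replication and the nucleoid (0.00176) passed on the flagellar side, as they did with a dye term (0.00366 each) and with camera on ranks (0.00613 and 0.00572). With an estimated correlation neither passed after centring (adjusted p = 0.44 each). Of 19 translation factor and RNA polymerase genes (adjusted p = 0.0559, median 0.77), 11 passed on that side, also adjusted over the list alone and after centring. The release factor genes prfC (1.47 ± 0.13) and prfA (1.41 ± 0.34) and tufA (1.36 ± 0.25), which has a near-identical copy in tufB, led it. Of 25 genes for DNA replication and the nucleoid (adjusted p = 0.0586, median 0.82), 14 passed on the flagellar side and 2 on the iron uptake side (17 and 2 adjusted over the list alone, and 17 and 4 after centring). fis lay at 1.75 ± 0.27, stpA at 1.71 ± 0.06 and gyrA at 1.18 ± 0.18, whose call was lost without array 1 (adjusted p = 0.0582). Of 20 genes of the TCA cycle (adjusted p = 0.08, median 0.77), 11 passed on the flagellar side and 1 on the iron uptake side, also adjusted over the list alone, and 12 and 4 after centring, with the succinate dehydrogenase genes sdhA (2.06 ± 0.51), sdhD (2.05 ± 0.39) and sdhC (1.85 ± 0.28) furthest out. Of 27 genes of glycolysis and the pentose phosphate pathway (adjusted p = 0.387, median 0.25), 9 passed on the flagellar side and 3 on the iron uptake side (10 and 3 adjusted over the list alone and after centring), and the members of largest size on the deposited scale were edd at 1.73 ± 0.68, pykA at 1.47 ± 0.03 and gpmM at 1.46 ± 0.27.

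In the remaining lists for nutrients, large values of single genes lay on both sides. Of 25 phosphate and magnesium genes (adjusted p = 0.072, median -0.32), 2 passed on the flagellar side and 4 on the iron uptake side, also adjusted over the list alone, and 2 and 9 after centring. After phoH, the glycerol phosphate uptake genes ugpA (-2.43 ± 0.19) and ugpB (-2.17 ± 0.15) had the largest sizes. Of 29 genes for glutamate and nitrogen control (adjusted p = 0.421), 8 passed on the flagellar side and 9 on the iron uptake side (9 and 9 adjusted over the list alone, and 10 and 9 after centring). There the median of 0.11 and the mean of -0.21, relative to the median and the mean of all genes, differed in sign. The largest sizes were those of glnK at -2.75 ± 0.78, astC at -2.27 ± 0.12 and nac at -2.24 ± 0.66. Of 40 genes for arginine, histidine and aromatic amino acids (adjusted p = 0.104, median 0.47), 19 passed on the flagellar side and 3 on the iron uptake side, also adjusted over the list alone, with hisG at 2.44 ± 0.21, carA at 2.03 ± 0.52 and hisD at 1.66 ± 0.38. After centring that list passed (camera adjusted p = 0.0346, and 0.52 with an estimated correlation), with 18 genes on the flagellar side and 6 on the iron uptake side. Of 34 genes for methionine and cysteine (adjusted p = 0.29, median 0.23), 11 passed on the flagellar side and 1 on the iron uptake side, also adjusted over the list alone, and 12 and 7 after centring. The sulfate assimilation genes cysJ (2.49 ± 0.55), cysA (2.15 ± 0.37) and cysI (1.98 ± 1.42) had the largest sizes on the deposited scale. The deposited ratio of cysI was largest on array 2 (4.09, against 1.545 and 1.042 on turned arrays 1 and 3), and its call was lost with a dye term.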

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

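The comparisons in this part were chosen after the arrays had been seen. Spots with no single named gene, which the gene tests leave out, also held large ratios. Of 5676 such spots measured on all 3 arrays, 1756 (30.9%) had at least a 2-fold size and 1 sign on the 3 arrays, with 360 on the flagellar side and 1396 on the iron uptake side. Among spots of named genes 29.4% did so. These values are centred on the median named gene, against which the unnamed spots had a median of -0.54. Of the 101 spots taken to have almost no signal (median -0.44), 96 were unnamed. The split between the sides depended on the centre, with 508 and 929 spots on the flagellar and iron uptake sides uncentred, and 846 and 709 (27.4% in all) when each array was centred on the unnamed spots. No biological explanation was tested, since the annotation used here does not say which of these spots stand for genes of this strain.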

How the results depend on the processing

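Alternatives with no-signal marks kept, with genes measured on all spots, with centring and array 2 left out together, with other centres for unnamed spots, and with fewer RyhB targets were added after seeing the data. Direction of triclosan against untreated stays open, and turning all arrays round changes no size by construction. With array 3 turned the other way round, limma called 0 genes on either side (3 at an unadjusted p under 0.05), 14 genes changed 2-fold and the median r was -0.838. Of the named genes, sodA, soxS and wzxC then changed sides, at mean log2 sizes on the deposited scale of 0.059, 0.031 and 0.317. The cold shock list's median stayed on its side at 0.319 while camera's sign turned (adjusted p = 0.963). Camera then called 9 lists, without those for flagella (0.969), branched chain amino acids (0.345), purines and pyrimidines (0.086), aerobic respiration (0.086) and fatty acid synthesis (0.082), and newly with lipopolysaccharide, peptidoglycan and arginine. As the arrays were oriented by their correlations, few calls follow by construction. The ordinary statistic called 0 genes (689 at an unadjusted p under 0.05). Its spread rests on 2 degrees of freedom and also holds the arrays' offsets, and the part of each was not tested.

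Of 1222 genes (834 flagellar, 388 iron uptake side), single spots gave 2232 (1512 and 720, counting spots), the lists' genes alone 544 (404 and 140, fewer genes tested) and marks kept 569 (401 and 168, with 538 shared). Array weights called 1369 on the flagellar side. Centring called 875 on the iron uptake side, and with array 2 left out as well 1960 in all and 965 there. Leaving out 1 array gave 637 to 1272 genes, 376 to 1021 on the flagellar and 251 to 317 on the iron uptake side. The 967 genes at 2-fold became 1924 as single spots, 1529 at 1.5-fold and 878 to 1162 with 1 array left out. Of 35 lists, 13 passed, against 20 with a dye term, centred, at an adjusted p of 0.1 or centred without array 2, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (9), and 13 to 20 with 1 array left out. Median r was 0.572 with marks kept, 0.937 centred without array 2 and 0.821 to 0.937 with 1 array left out. Where no cause is named, the cause was not tested.

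Of 121 named genes, 16 lost their call without array 1, 11 without array 2, 5 without array 3, 5 with a dye term (aceK, cysI, sodA, wcaI and wzxC) and 4 with treat (aceK, lptE, rnc and uvrD). With marks kept 26 did: accC, bamD, cfa, clsB, csgD, envR, fabA, fabH, fadH, gadA, gpsA, grxD, gyrA, ibpA, lptE, lpxH, mprA, mqsR, msbA, nfsB, ppiD, rnc, rpoS, uvrD, wcaI and wzxC. The losses with 1 array left out are on the deposited scale, where the arrays' offsets enter the spread. Centred without array 2, 117 of the 121 named genes kept their status and 4 gained a call. Centred fits without array 1 or array 3 were not run. Centring ended the call of wcaI and of the carbohydrate list, which was also lost with a dye term (adjusted p = 0.119), on ranks (0.0524), with array 3 turned (0.086) and centred without array 2 (0.109). Single spots and genes on 2 arrays gave no list result, and the comparison with probes of other strains was not run. No paired analysis was possible because there is 1 group and each array already pairs both RNAs. Brightness over background was not used here, so weak spots were not filtered by it.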

Other observations

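Outside the fixed lists, genes of large size lay on both sides, and those in this paragraph were picked after their values were seen, with no test of any group they form. On the iron uptake side lay iscR, the regulator of iron-sulfur cluster assembly, at -3.59 ± 0.17 (SD, n = 3), and yddB and yncE, at -3.60 ± 0.35 and -3.42 ± 0.04. On the flagellar side lay the nickel uptake genes nikD (3.12 ± 0.39) and nikE (2.00 ± 0.33) with their regulator nikR (2.20 ± 0.07), the hydrogenase maturation genes hypB (1.74 ± 0.36) and hypC (1.82 ± 0.43), and the copper efflux genes cusB (2.04 ± 0.47) and cusC (1.87 ± 0.81). The spermidine genes potA (2.08 ± 0.25), potB (2.13 ± 0.23), speD (1.98 ± 0.26) and speE (1.73 ± 0.14) and adk for adenylate kinase (2.50 ± 0.64) lay there too. Each of those with a value here passed the threshold of limma and had 1 sign on the 3 arrays. Of 18 runs of at least 5 neighbouring genes that passed after centring with a log2 size of at least 1, 12 lay on the flagellar side and 6 on the iron uptake side. The highest number in 200 shuffles of the gene order was 1. The longest run held 18 ribosomal protein genes, and 3 runs held no list member: cusR to pheP and hypA to hypE on the flagellar side, and rimL to ydcL, with tehA and tehB, on the iron uptake side.

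The tests in the rest of this part were chosen after the result was seen. The mirror image between array 3 and the other arrays was set against 2 dye effects. A dye bias of each oligonucleotide would leave neighbouring genes no more alike than shuffled ones, yet next genes on the chromosome had r = 0.57 over 2318 pairs, against at most 0.059 in 1000 shuffles, which argues against it as the whole pattern. A dye bias that runs one way with signal would put weak spots at one end of the values. In the data 29 of 45 iron uptake genes lay below the 5th percentile (-1.30) of 101 spots taken to have almost no signal. The ribosomal proteins' median of 1.37 lay above the weak spots' median of -0.44. The weak spots were chosen by their ratios, of whole numbers up to 5 on each array, which bounds their values. They could not reach the far ends, so this comparison cannot decide on a bias that runs with signal. A difference between the RNAs of treated and untreated cells stays an open hypothesis, as does such a bias. The weak spots' own shift leaves small values on the iron uptake side uncertain.

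The marks for no signal bear on how the ratios were formed. All 532 marks on arrays 1 and 2 were negative and all 153 on array 3 were positive. A plain ratio of one dye over the other on every array, marked where the upper channel is empty, would give 1 sign throughout, and the 153 positive marks argue against it. A second reading, in which either channel can be marked and 1 RNA pool alone reached no signal, was taken to put nearly all weak spots on the marks' side. Of 1326 readings at an exact ratio of 2 or 3 to 1, pooled over the 3 arrays, 58.1% lay on the other side. At 2 to 1, readings on the other side and on the marks' side were 112 and 88 on array 1. They were 184 and 231 on array 2, and 187 and 74 on array 3. These readings were not chosen by signal, so they do not decide on the second reading. A candidate explanation that was not tested further is that ratios of one RNA over the other were formed first and the sign of array 3 was turned later. It leaves open which RNA was on top, and with it the direction of every value.

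Several genes for proteins that use or store iron lay on the other side from most iron uptake genes, while the uptake genes feoA, feoB and feoC lay on the flagellar side. RyhB is a small RNA under Fur that lowers mRNAs of iron-using proteins, and its targets may therefore lie against the uptake genes. Of 18 targets measured, 13 passed on the flagellar side after centring and 3 on the iron uptake side, with a median of 0.79. The list was written after sodB, sdhA, sdhC, sdhD and nirB had been seen. Over the other 13 targets the median of 0.57 lay above that of 96.25% of 10000 random lists of that size, short of the share asked for. Without ftnA and bfr, which are in the iron uptake list, and sdhB of the sdh operon, the median of 10 targets was 0.48 and the share 92.39%, so the test does not decide. The 3 on the iron uptake side, iscU, iscA and erpA, serve iron-sulfur cluster assembly, as iscR does.

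The 3 arrays allow 4 patterns of signs, so the share of patterns with as many genes as the real one cannot fall under 0.25. The arrays were oriented by their correlations, so the few calls of the other patterns were set in advance and decide nothing about chance. Only 1 pattern, the real one, called 1222 genes on the deposited scale, where the highest other called 0, and 1781 after centring, where the highest other called 0 (limma; with array 3 turned, 3 genes had an unadjusted p under 0.05).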
